A study of Danio rerio with 12 samples.

How the data were processed

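The counts per gene and the TPM values (transcript levels scaled by gene length and depth) per gene were deposited by the authors, per the file headers, for 25281 genes in 12 libraries, and all 24 value columns were used. The submitters' processing notes name GRCz11 as the assembly; aligner, counting program and annotation release are not given in the sources used here. TPM matched counts divided by length within 0.1% for 71.9% of values with at least 50 counts. Gene identifiers, positions and symbols came with the deposited values, 1194 symbols carry a running number because the name occurs more than once, and 2221 genes had 0 counts in every library. The libraries came from a low-input full-length method (SMART-Seq HT with Nextera XT) on sorts of at most 1000 cells. The method does not mark the strand, so reads of overlapping genes cannot be assigned to one of them, and counts of close paralogs depend on how the submitters treated ambiguous reads. Reads from amplified cDNA are not independent molecules, so intervals on count ratios cover counting error only.

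Counts were analysed with edgeR 4.0.16 (quasi-likelihood, robust), limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. Main settings, fixed before the data were examined, were TMM normalisation, the default expression filter, Benjamini-Hochberg adjustment at 0.05, and a separate fit of the 6 libraries of each time; the contrasts between times used all 12 libraries. Larvae were depigmented with PTU from 0.25 to 5 days post-fertilisation. Ratios with 0 counts in a group are bounds over a floor of 3 counts in each library of that group. Named genes had an adjusted p under 0.05, no overlap between conditions, a higher group mean of at least 10 CPM and a symbol that is not a placeholder, and were the 10 highest and 10 lowest log2 fold changes (5 for contrasts between times). At 4 dpi 257 and 230 genes met this rule. Where fewer than 3 qualified in a direction, the 5 smallest unadjusted p were named. Results for some genes are not reported here.

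At 2 dpi libraries with the same replicate number share a date in their titles, so a block by number gives the comparison within dates. Whether a date is that of sorting, library or sequencing is not given in the sources used here. All libraries at 4 dpi carry 1 date, and whether the numbers there pair libraries is not given, so they were not taken to. After group means were removed, libraries with the same number correlated at r = 0.60, 0.03 and 0.57 at 2 dpi (other pairs -0.60 to 0.21). The first 3 principal components held 38.8%, 18.3% and 10.3% of the variance. Time goes with larval age and with date.

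Gene lists were written from general knowledge before the data were examined, and 1177 of 1259 symbols were found, 19 of them through the reference name tables. The 32 lists were macrophage identity, microglia, inflammatory cytokines and mediators, resolution and repair, phagocytosis and efferocytosis, lysosome, lipid handling, retinoid processing, type I interferon response, antigen presentation, complement, cell cycle, glycolysis, oxidative phosphorylation, cytosolic ribosome, mitochondrially encoded genes, immediate early and heat shock genes, p53 and DNA damage, oxidative stress and iron, chemokine receptors and migration, extracellular matrix and proteases, RPE, photoreceptor, Müller glia, inner retinal neuron, neutrophil, lymphocyte and NK, erythrocyte, vascular and mural, epithelium and cornea, lens, and iridophore and other pigment cells. The oxidative phosphorylation, cytosolic ribosome, mitochondrially encoded and lens lists took every gene whose symbol has a given form, so genes with related names are among them. The mitochondrially encoded and the immediate early and heat shock lists were classed as measures of sample quality. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 on log2 CPM, and again with an estimated correlation and with fry.

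In a trial, counts were simulated for each gene independently and fold changes were planted in them. It recovered none of the genes planted at log2 1, 2 or 3 at 2 dpi or in the difference between the times. At 4 dpi it recovered 1.49%, 31.3% and 50%. A planted list of 60 genes was called by camera at both times (adjusted p = 3.60e-16 and 4.71e-29). With an estimated correlation its adjusted p was 0.0368 and 0.00407, and with fry 0.0534, not called, and 0.000790. By camera, of 30 random lists 1 was called at 2 dpi and 0 at 4 dpi. The simulated genes were independent, so these rates do not carry over to lists whose members move together. The estimated correlation of the real cell cycle list was 0.326 at 2 dpi and 0.529 at 4 dpi. Alternatives tried were DESeq2's size factors, no filter and a strict filter (1 CPM and a mean of 50 counts), DESeq2, limma voom with quality weights, limma on log2(TPM + 1) with a TPM of at least 1 in 3 libraries, a block by replicate number, omission of each library, all 12 libraries in the fit or only the 6 of a condition, a fold change threshold, a photoreceptor covariate, and omission of libraries above 4% of photoreceptor counts.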

Results

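Macrophages and microglia were purified from zebrafish larval eyes as cells carrying the red fluorescent protein mCherry, in sorts of at most 1000 cells. Their RNA was amplified and sequenced. In 6 of the 12 libraries the retinal pigment epithelium (RPE), the pigmented layer behind the photoreceptors, had been ablated genetically by treating larvae with 10 mM metronidazole for 24 h from 5 to 6 days post-fertilisation. The other 6 libraries came from larvae that received no drug, so the drug and the ablation could not be told apart. Each condition was sampled at 2 and at 4 days post-injury (dpi), with 3 libraries per condition and time. The question was how the immune cells of the eye respond to loss of the RPE, and whether the response differs between the times. Libraries held 19791633 to 38935355 counts and 16299 to 19601 detected genes, with 2.98% to 3.95% of counts from mitochondrially encoded genes. Unablated libraries held 19791633 to 35469597 counts at 2 dpi and 20778047 to 32585600 at 4 dpi. Ablated libraries held 30536425 to 38935355 and 31730109 to 35258088. Unless a log2 value is given, levels are means ± SD in CPM (counts normalised to library size) over n = 3 libraries. Log2 fold changes (ablated over unablated) carry their standard error (SE). Nothing in the labels says that replicates came from separate pools of animals, so p-values measure the spread between these samples, which may be technical.

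The ablated tissue and the sorted cells were examined first. rpe65a (ENSDARG00000007480, GRCz11 chromosome 2, 1428696 to 1443692), the RPE isomerase of the visual cycle, gave 439 counts in the unablated and 1 count in the ablated libraries at 4 dpi, a ratio of 0.00196 (95% interval 4.95e-05 to 0.0110, counting error only), and fell at that time (edgeR adjusted p = 0.0498). At 2 dpi it gave 6609 and 4 counts (log2 fold change -11.41, SE 3.14, edgeR adjusted p = 0.155), of which 6482 came from unablated replicate 2, at 350 CPM. Unablated replicates 1 and 3 held 28 and 99 counts. The pan-macrophage gene mpeg1.1 was abundant in every group and did not pass the test. It stood at 2204 ± 507 CPM in unablated and 2201 ± 378 CPM in ablated libraries at 2 dpi. At 4 dpi it stood at 2669 ± 352 and 2232 ± 428 CPM. The colony-stimulating factor receptor genes csf1ra and csf1rb, the microglial receptor gene p2ry12 and the apolipoprotein gene apoeb did not pass at either time either. Their log2 fold changes were 0.84, -0.38, 0.44 and -0.57 at 2 dpi and -0.02, -0.32, 0.14 and -0.46 at 4 dpi. The same held for il1b (-0.57 and -0.76), tnfa (0.32 and -0.86), il10 (-0.44 and 0.13) and il34 (1.84 and 0.63).

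RNA of photoreceptors was present in the sorts and differed between libraries. The share of counts from the photoreceptor list was 16.0%, 14% and 0.145% in unablated replicates 1, 2 and 3 at 2 dpi, against 2.06%, 0.330% and 0.114% in the ablated ones. At 4 dpi it was 0.785%, 0.122% and 0.866% in unablated and 0.0995%, 4.25% and 0.0842% in ablated libraries. The rod opsin gene rho therefore averaged 32408 ± 36685 CPM in unablated and 850 ± 1465 CPM in ablated libraries at 2 dpi (log2 fold change -5.25, SE 3.76, edgeR adjusted p = 0.513). At 4 dpi it averaged 1479 ± 2485 and 6414 ± 11107 CPM (2.12, SE 3.66, edgeR adjusted p = 0.827).

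**Figure D1:**
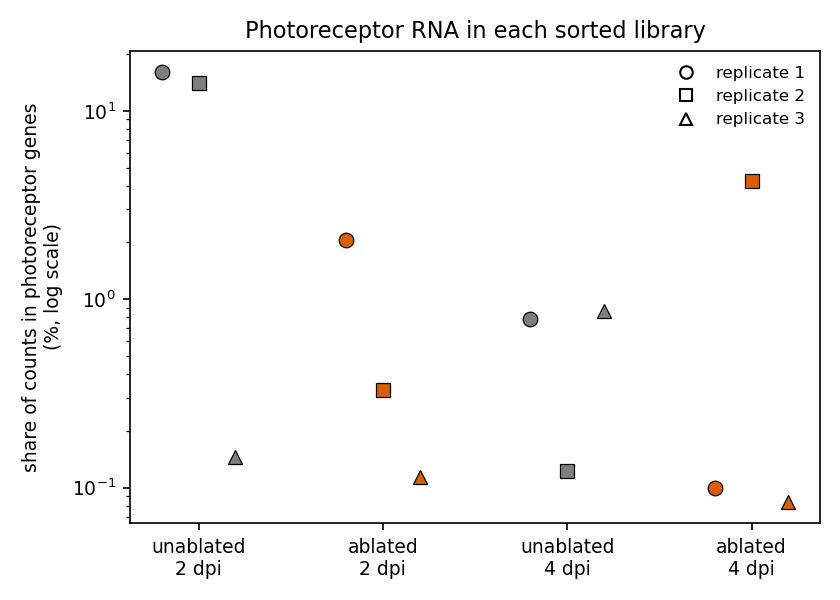
Share of counts from the photoreceptor gene list (percent, log axis) in each of the 12 libraries, by condition and time, with each point a library. The 2 highest libraries, at 16.0% and 14%, were both unablated at 2 dpi, and the next, at 4.25%, was ablated at 4 dpi.

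At 2 dpi, genes of cell division were higher in the sorts from ablated eyes. All 77 measured members of the cell cycle list were higher in ablated libraries, with a median log2 fold change of 2.15 (quartiles 1.72 and 2.40). The list rose (camera adjusted p = 2.09e-33; adjusted p = 0.510 with an estimated correlation). The mean log2(CPM + 1) of the list was 6.05, 6.42 and 5.98 in ablated replicates 1 to 3 and 3.65, 4.24 and 4.56 in the unablated ones. Examples were the mitotic cyclin gene ccna2 (ENSDARG00000011094, 19.2 ± 4.7 to 132 ± 22 CPM, log2 fold change 2.78, SE 0.28), the kinetochore gene nuf2 (3.05, SE 0.35), the spindle midzone gene prc1b (3.14, SE 0.38) and the nucleotide enzyme gene dut (2.21, SE 0.28). The proliferation marker mki67 (ENSDARG00000091150, chromosome 12, 10366617 to 10381282) stood at 33.4 ± 19.8 CPM in unablated and 181 ± 79 CPM in ablated libraries (2.44, SE 0.66, edgeR adjusted p = 0.150). No member passed over all genes tested. Adjusted over the list alone 64 passed, all higher.

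No gene passed the test at 2 dpi. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 16048 genes (smallest adjusted p = 0.0726). At an unadjusted p under 0.05 there were 2691 genes, of which 1930 were higher and 761 lower in ablated libraries. DESeq2 called 1486 genes, limma voom with quality weights 976, limma on log2(TPM + 1) 852, and edgeR with all 12 libraries in the fit 1142. The 3 ablated libraries all lay above or all below the 3 unablated ones for 26.7% of genes, where the mean over all such splits is 10%. Genes move together, so a single split can exceed that mean without any effect. The shares of the other splits were not computed. The genes with the smallest p, none past the threshold, included the small GTPase gene rnd3a (ENSDARG00000076799, chromosome 22, 12431608 to 12449572), at 61.3 ± 2.1 CPM in unablated and 246 ± 10 CPM in ablated libraries (log2 fold change 2.00, SE 0.16, edgeR adjusted p = 0.0726). With it came the prostaglandin reductase gene ptgr1 (1.94, SE 0.16), the folate-cycle gene shmt1 (2.21, SE 0.19), cyb5b (2.53, SE 0.23) and the nucleolar chaperone gene npm3 (1.68, SE 0.16). On the lower side stood mob2b (-1.56, SE 0.21, edgeR adjusted p = 0.0732), the phospholipid transfer gene pltp (-2.70, SE 0.42), fam43a (-1.77, SE 0.28), the phosphodiesterase gene pde4ba (-1.06, SE 0.17) and ube2h (-1.63, SE 0.28).

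Of the 32 gene lists, 10 were called at 2 dpi, 6 up and 4 down, none of them with an estimated correlation. Beside the cell cycle, the neutrophil list rose (median 1.54, 10 of 13 members higher, camera adjusted p = 0.00862; adjusted p = 0.510 with an estimated correlation). Its members nccrp1 (1.81, SE 0.21), the metalloproteinase inhibitor gene timp2b (3.72, SE 0.47), the proteoglycan gene srgn (2.04, SE 0.30) and the interleukin 6 receptor gene il6r (1.54, SE 0.29) were among 6 that passed when adjusted over the list alone. The neutrophil peroxidase gene mpx, with 268 and 1294 counts in ablated replicates 1 and 3 and 0 in the other libraries of that time, was not tested at 2 dpi. The complement list rose (median 0.57, 12 of 17 higher, camera adjusted p = 0.0419). Its factor B homologue cfbl stood at 2.85 (SE 0.67), and 2 members passed when adjusted over the list alone. The macrophage identity list rose (median 0.34, 20 of 29 higher, adjusted p = 0.0332). The cathepsin S gene ctss2.1, at 1.24 (SE 0.22), was the 1 member past when adjusted over the list alone. The list of oxidative phosphorylation rose (median 0.25, 76 of 95 higher, camera adjusted p = 0.000154, with atp5if1a at 1.29, SE 0.25). So did that of the cytosolic ribosome (median 0.27, 83 of 94 higher, camera adjusted p = 3.28e-06, with rpl7l1 at 1.36, SE 0.16). Both lists took members by the form of their symbol and not by known function. Adjusted over the list alone, 0 and 1 of their members passed. For these 4 lists the adjusted p was 0.840 with an estimated correlation.

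Markers of other eye cells were lower at 2 dpi. The lists of photoreceptors (median -3.63, all 56 lower, camera adjusted p = 0.0289), inner retinal neurons (-3.19, 37 of 38, 0.000199), Müller glia (-1.83, 19 of 20, 0.0260) and epithelium and cornea (-1.98, 28 of 31, 0.000164) fell, each with an adjusted p = 0.840 with an estimated correlation. No member passed when adjusted over the list alone. Examples were the blue cone opsin gene opn1sw2 (4110 ± 3578 to 361 ± 256 CPM), the neuronal gene tfap2b (log2 fold change -7.42, SE 1.72), the gap junction gene cx43 (-1.20, SE 0.51) and the keratin gene krt17 (-2.64, SE 0.80). Unablated replicates 1 and 2, the libraries with 16.0% and 14% of photoreceptor counts, weighed on these calls. With DESeq2's size factors the macrophage identity, photoreceptor and Müller glia calls were lost (adjusted p = 0.0786, 0.153 and 0.0655), and with a photoreceptor covariate, which removes the photoreceptor list by construction, the Müller glia call (0.761). Without unablated replicate 1 alone 6 lists were called. Those of macrophage identity, complement, ribosome, photoreceptors and Müller glia were lost (adjusted p = 0.215, 0.111, 0.0615, 0.843 and 0.117). The photoreceptor and Müller glia calls were also lost without unablated replicate 2 (0.458 and 0.0722) and without ablated replicate 3 (0.314 and 0.184). The complement call was lost without ablated replicate 3 (0.0569), macrophage identity without ablated replicate 1 (0.0681), and the epithelial call without unablated replicate 3 (0.195).

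With the title date as a block at 2 dpi, 5 more lists were called. Retinoid processing and the RPE fell (adjusted p = 4.08e-05 and 0.000224, against 0.0784 and 0.350 without the block), as did immediate early and heat shock genes (0.0449 against 0.103). The lysosome and chemokine receptors and migration rose (0.00862 against 0.120, and 0.0449 against 0.121). Without the block all 5 had an adjusted p = 0.840 with an estimated correlation. Their medians were -1.90, -3.30, -0.60, 0.32 and 0.15. In the retinoid list dhrs3b stood at -4.77 (SE 1.74), and rlbp1b at -10.32 (SE 3.62). Among the RPE genes slc16a8 stood at -4.09 (SE 1.07) and mitfa at 2.00 (SE 0.44). The lysosomal proton pump gene atp6v1ab stood at 1.06 (SE 0.18) and the early response gene btg2 at -2.32 (SE 0.53). The other 17 lists were not called at 2 dpi. Their medians and camera adjusted p were -0.32 and 0.484 for microglia, -0.46 and 0.0673 for inflammatory cytokines and mediators, 0.31 and 0.663 for resolution and repair, and -0.10 and 0.663 for phagocytosis and efferocytosis. They were -0.27 and 0.350 for lipid handling, 0.20 and 0.663 for the type I interferon response, -0.34 and 0.484 for antigen presentation, -0.42 and 0.663 for glycolysis, and -0.03 and 0.909 for mitochondrially encoded genes. They were -0.35 and 0.142 for p53 and DNA damage, 0.07 and 0.454 for oxidative stress and iron, and -0.31 and 0.913 for extracellular matrix and proteases. For the remaining cell types they were -0.66 and 0.704 for lymphocytes and NK cells, -0.44 and 0.909 for erythrocytes, -0.54 and 0.679 for vascular and mural cells, where camera pointed upward, -2.16 and 0.142 for the lens, and 0.73 and 0.130 for iridophores and other pigment cells. Single omissions called 6 of the 22 lists not called without a block: inflammatory genes downward without unablated or ablated replicate 1 (adjusted p = 0.0223 and 0.0201) and the lysosome upward without unablated or ablated replicate 3 (0.00740 and 0.000195). The rest came without unablated replicate 3: chemokine receptors (7.70e-05), oxidative stress and iron (0.00864), the RPE (0.0113) and retinoid processing (0.000131). Adjusted over the list alone, 8 matrix and protease genes passed as higher, among them mmp2 (1.88, SE 0.29) and adam8a (4.13, SE 0.71), and 2 as lower.

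**Figure D2:**
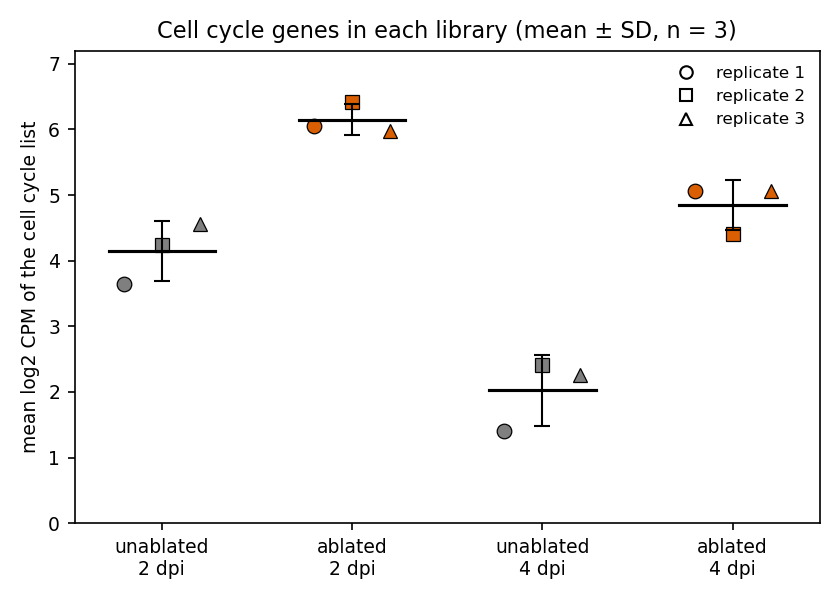
Mean log2(CPM + 1) of the 77 cell cycle genes in each library, by condition and time, with each point a library and the bars the group mean ± SD. Ablated libraries lie at 5.98 to 6.42 at 2 dpi and 4.41 to 5.07 at 4 dpi, above the unablated ones at 3.65 to 4.56 and 1.41 to 2.41.

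At 4 dpi cell division genes were again higher after ablation, and by then single genes passed the test. The cytokinesis motor gene kif23 (ENSDARG00000014943, chromosome 18, 20435821 to 20458840) had 0 counts in the 3 unablated libraries and 27.4 ± 10.5 CPM in the ablated ones. It was at least 249-fold higher over a floor of 3 counts in each library (edgeR adjusted p = 0.0193). The condensin gene ncaph rose from 0 to 19.4 ± 7.9 CPM (at least 177-fold) and the spindle gene aspm from 0 to 17.5 ± 10.0 CPM (at least 159-fold). The nucleotide pyrophosphatase gene dctpp1 rose from 0 to 10.1 ± 6.7 CPM (at least 91.8-fold). The edgeR adjusted p were 0.0207, 0.0286 and 0.0360. haus4, of the spindle augmin complex, gave 1 count against 1389 (ratio 1195, 95% counting interval 214 to 47237) and the replication stress gene etaa1 2 against 1180 (508, 140 to 4197). The mitotic cyclin gene ccnb1 (ENSDARG00000051923, chromosome 5, 54711027 to 54714789) rose from 0.0700 ± 0.0690 to 28.6 ± 14.3 CPM (log2 fold change 8.76, SE 0.87, edgeR adjusted p = 0.0188). The kinetochore gene spc25 rose too (5.44, SE 0.60). mki67 rose from 4.99 ± 2.64 to 64.2 ± 16.5 CPM (3.69, SE 0.52, edgeR adjusted p = 0.0286). The lubricin gene prg4a (5.10, SE 0.97) and lrrc15 (4.26 ± 3.42 to 90.6 ± 11.4 CPM, 4.40, SE 0.74) completed the 10 genes named for the largest rise.

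Most genes that fell at 4 dpi moved with the epithelial adhesion gene epcam from library to library. Looked at after the calls were seen, 190 of the 306 genes other than epcam that fell (62.1%) followed epcam across the 12 libraries with group means removed at r over 0.7. Of the 298 that rose 4 did (1.34%) and of all genes tested 5.96%, so these falls do not by themselves show a response within macrophages. Within groups epcam varied mainly at 2 dpi, at 173, 1166 and 3631 CPM in unablated and 217, 32.5 and 805 CPM in ablated libraries. At 4 dpi it ranged from 1030 to 1181 and from 91.6 to 282 CPM. The correlations therefore rest mostly on the 2 dpi libraries, not on those where the falls were called. The transporter gene mfsd4aa (ENSDARG00000023768, chromosome 11, 38429319 to 38458406) fell from 22.0 ± 11.3 to 0.109 ± 0.091 CPM (log2 fold change -7.60, SE 0.89, edgeR adjusted p = 0.0213). The retinaldehyde-binding gene rlbp1b (-4.91, SE 0.88), the keratin gene krt18a.1 (-4.90, SE 0.51) and the receptor gene gpr184 (-4.80, SE 0.58) fell as well. The guanylate cyclase gene gucy2c fell from 166 ± 51 to 7.52 ± 6.95 CPM, and with it the interleukin 17 pathway genes traf3ip2l (109 ± 36 to 5.83 ± 3.00 CPM, log2 fold change -4.22, SE 0.52) and il17rc (-4.01, SE 0.73). tnks1bp1 (-3.86, SE 0.65), sytl1 (-3.78, SE 0.53) and the interferon signalling gene stat1b (36.7 ± 3.7 to 2.81 ± 1.89 CPM, -3.70, SE 0.64) completed the list. Of these 10, gpr184, gucy2c, traf3ip2l, il17rc and sytl1 followed epcam (r = 0.871, 0.951, 0.817, 0.837 and 0.921), and the other 5 did not (r = -0.644 to 0.129).

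In all, edgeR's quasi-likelihood test called 605 of 16313 genes at 4 dpi, 298 higher and 307 lower, with 3371 genes at an unadjusted p under 0.05. Each of the 605 separated all 3 ablated from all 3 unablated libraries, as did 30.5% of all genes. The mean over all such splits is 10%, which a single split can exceed without any effect because genes move together. DESeq2 called 2317 genes, limma voom 1553, limma on log2(TPM + 1) 1672, and edgeR with all 12 libraries 222 (197 higher, 25 lower). With a block by replicate number, which may or may not pair libraries at 4 dpi, edgeR called 0. The count of 605 changed with the omission of any library. It was 5 without unablated replicate 1, 38 without unablated replicate 2 and 24 without unablated replicate 3. It was 0 without ablated replicate 1 and 0 without ablated replicate 3. Without ablated replicate 2, the library with 4.25% of photoreceptor counts, it rose to 1420.

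The cell cycle list rose at 4 dpi with a median of 3.53 (76 of 77 higher, 18 past over all genes and 52 when adjusted over the list alone, camera adjusted p = 2.49e-27; adjusted p = 0.284 with an estimated correlation). Its clearest members were the condensin gene ncapd2 (3.02 ± 0.18 to 35.9 ± 1.0 CPM, log2 fold change 3.57, SE 0.21, edgeR adjusted p = 0.00872) and the ribonucleotide reductase gene rrm1 (2.99, SE 0.25). Genes of oxidative phosphorylation rose by less, and nearly all together. Of 96, 93 were higher, 16 past over all genes and 63 when adjusted over the list alone (median 0.51, camera adjusted p = 4.96e-24; adjusted p = 0.284 with an estimated correlation). Among them were cyc1 of complex III (206 ± 20 to 363 ± 14 CPM, 0.82, SE 0.12) and the cytochrome oxidase gene cox8b (2.38, SE 0.35). The mitochondrially encoded list rose too (median 0.27, all 13 higher, 0 past over all genes and 6 when adjusted over the list alone, camera adjusted p = 5.72e-05; adjusted p = 0.284 with an estimated correlation). So did the cytosolic ribosome (median 0.14, 82 of 94 higher, camera adjusted p = 0.000245; adjusted p = 0.607 with an estimated correlation). Its 1 member past over all genes was rpl22l1 (0.89, SE 0.15), and none passed when adjusted over the list alone. The ribosome call was lost without ablated replicate 1 (adjusted p = 0.0610).

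Complement genes rose at 4 dpi (median 1.39, 13 of 16 higher, camera adjusted p = 0.000864; adjusted p = 0.284 with an estimated correlation). Over all genes 4 rose and 1 fell, and adjusted over the list alone 5 and 1. c1qa (23.9 ± 5.5 to 114 ± 33 CPM, log2 fold change 2.25, SE 0.29) and c1qc (1.36, SE 0.24), which encode C1q chains, and the properdin gene cfp (1.82, SE 0.20) rose, and the complement receptor subunit gene itgam fell (-2.39, SE 0.36). The neutrophil list rose (median 1.05, 11 of 14 higher, 4 past over all genes and 7 when adjusted over the list alone, camera adjusted p = 0.000671; adjusted p = 0.284 with an estimated correlation). Its risers were nccrp1 (118 ± 3 to 325 ± 23 CPM, 1.46, SE 0.11), il6r (1.71, SE 0.15), csf3r, the granulocyte colony-stimulating factor receptor gene, and scpp8 (3.96, SE 0.66). mpx itself stood at 0.765 ± 1.325 CPM in unablated and 5.22 ± 8.26 CPM in ablated libraries and did not pass (2.79, SE 2.65). In unablated replicates 1 to 3 it gave 0, 46 and 0 counts while nccrp1 averaged 118 CPM, so the rise of this list need not mean neutrophils. In the oxidative stress and iron list (median 0.47, 27 of 45 higher, camera adjusted p = 0.0296; adjusted p = 0.284 with an estimated correlation) members moved apart. The glutathione transferase gene gsto2 (1.54, SE 0.20) and the superoxide dismutase gene sod2 (1.07, SE 0.16) rose and the ferritin gene fth1a fell (1072 ± 53 to 297 ± 62 CPM, -1.85, SE 0.17). Adjusted over the list alone, 15 rose and 4 fell, and the list's call was lost without ablated replicate 1 (adjusted p = 0.0543).

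Immediate early and heat shock genes fell at 4 dpi (median -0.81, 35 of 51 lower, camera adjusted p = 0.00215; adjusted p = 0.299 with an estimated correlation). Over all genes 7 fell and 2 rose, and adjusted over the list alone 13 and 4. The list was classed as a measure of sample quality, so its fall need not be a response to ablation. The transcription factor gene egr1 fell from 1696 ± 362 to 297 ± 7 CPM (log2 fold change -2.51, SE 0.18, edgeR adjusted p = 0.0115). The phosphatase gene dusp2 (-2.93, SE 0.42), ier2a (-1.57, SE 0.24) and cebpd (-2.49, SE 0.39) fell too. Genes of lipid handling fell (median -0.37, 26 of 41 lower, camera adjusted p = 0.0262; adjusted p = 0.284 with an estimated correlation). Adjusted over the list alone, 7 were lower and 2 higher. The 4 past over all genes were the sterol regulators insig1 (-2.33, SE 0.25) and srebf2 (-1.08, SE 0.19), the carnitine palmitoyltransferase gene cpt1ab (-1.40, SE 0.14) and pltp (-2.23, SE 0.29). The lymphocyte and NK list fell (median -1.20, 14 of 17 lower, 4 past over all genes, 5 lower and 1 higher when adjusted over the list alone, camera adjusted p = 0.0274; adjusted p = 0.284 with an estimated correlation). Those that fell were dusp2, cd28 (-6.88, SE 1.22), gata3 (-2.57, SE 0.45) and runx3 (-2.13, SE 0.36). The lipid and lymphocyte calls were both lost without unablated replicate 3 (adjusted p = 0.0572 and 0.0608).

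Epithelial genes fell at 4 dpi (median -2.57, 33 of 35 lower, camera adjusted p = 1.96e-08; adjusted p = 0.284 with an estimated correlation). Of them 7 passed over all genes, and 15 lower and 1 higher did so when adjusted over the list alone. The adhesion gene epcam fell from 1126 ± 115 to 169 ± 89 CPM (log2 fold change -2.74, SE 0.38, edgeR adjusted p = 0.0286). The protease inhibitor gene spint1a (-2.51, SE 0.24) fell too, and icn, an S100 family gene, fell from 1820 ± 236 to 651 ± 95 CPM. Other cell type lists fell as well. They were Müller glia (median -1.19, 18 of 20 lower, 0 past over all genes and 4 when adjusted over the list alone, camera adjusted p = 0.00357; adjusted p = 0.284 with an estimated correlation) and the RPE (-0.95, 11 of 13, 2 and 4, 0.00583; adjusted p = 0.299 with an estimated correlation). Further ones were retinoid processing (-0.45, 21 of 31, 2 and 4, 0.0296; adjusted p = 0.299 with an estimated correlation) and inner retinal neurons (-0.75, 31 of 38, 0 and 0, 0.000390; adjusted p = 0.607 with an estimated correlation). rlbp1b and rpe65a were the members past in both the RPE and the retinoid lists. The retinoid call was lost without unablated replicate 1 (adjusted p = 0.0706) and without ablated replicates 1, 2 or 3 (0.0756, 0.0524 and 0.0698).

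**Figure D3:**
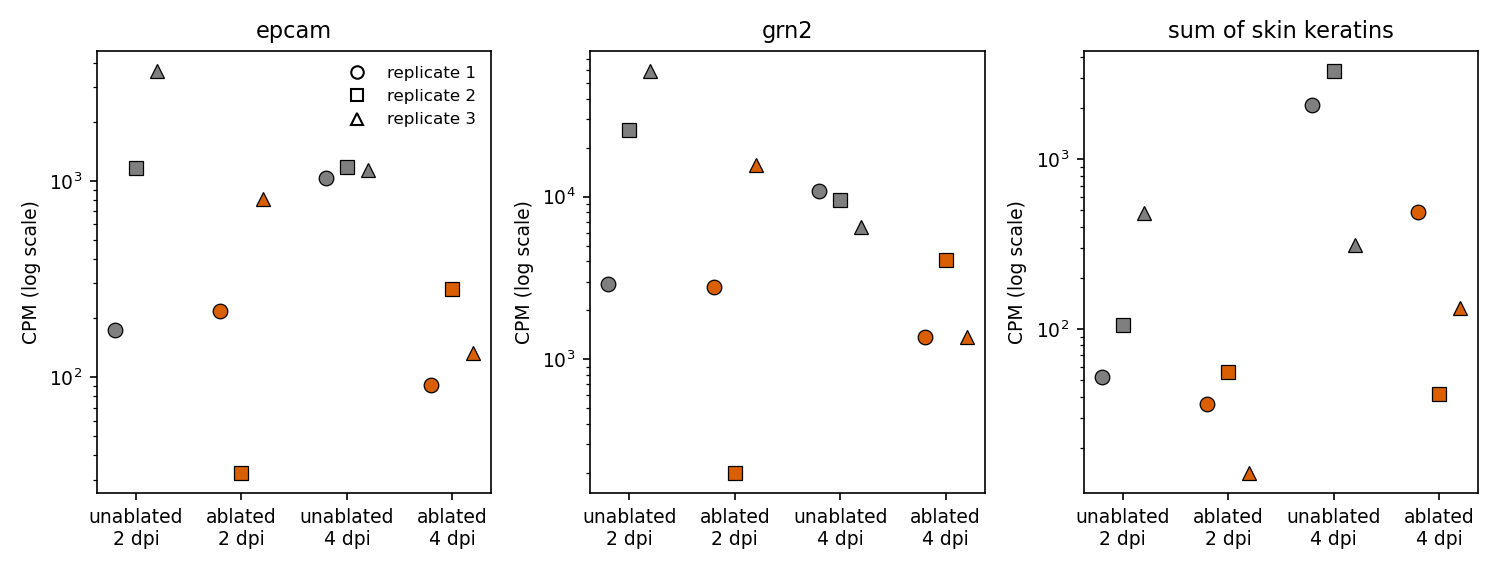
Levels of epcam, of the granulin gene grn2 and of the sum of skin keratins in each library (CPM, log axis), by condition and time, with each point a library. At 4 dpi epcam lies at 1030 to 1181 CPM in unablated and 91.6 to 282 CPM in ablated libraries, and grn2 at 6509 to 10779 and 1365 to 4099 CPM.

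The other lists were not called at 4 dpi, though single members passed. For macrophage identity (median 0.10, camera adjusted p = 0.0574), mfap4 (1.49, SE 0.20) rose with cfp and ncf1 fell (-0.71, SE 0.12). Without unablated replicate 2, ablated replicate 2 or unablated replicate 3 the list was called upward (0.0305, 0.00138 and 0.0106). For microglia (-0.18, 0.193) the 3 C1q genes rose, while bhlhe41 (542 ± 54 to 235 ± 32 CPM, -1.21, SE 0.15) and sall3a (-1.22, SE 0.21), which encode transcription factors, were among 4 that fell. Among inflammatory cytokines and mediators (-0.63, 0.112) the cyclooxygenase gene ptgs2b (-2.54, SE 0.42) and the chemokine gene ccl20a.3 (-2.91, SE 0.56) fell. In the type I interferon list (median 0.00, 0.734, camera pointing downward) irf7 (-1.57, SE 0.26) and stat1b fell. In antigen presentation (-0.53, 0.0747) so did psmb12 (-2.63, SE 0.43) and mhc1uka (-2.83, SE 0.55). tgfbi, which encodes a matrix protein induced by TGF-beta, rose in the resolution and repair list (-0.17, 0.881) and, with adam9 (1.22, SE 0.20), in the matrix and protease list (-0.79, 0.244), from 47.1 ± 21.4 to 249 ± 36 CPM. In these lists 1 and 2 members passed as lower. In glycolysis (0.13, 0.112) pgam1a (1.00, SE 0.12), the hexokinase gene hk2 (1.19, SE 0.18) and gpia (0.72, SE 0.14) rose. In the lysosome list (0.10, 0.144) grna rose (0.91, SE 0.18) and acp5a fell (-0.75, SE 0.14). In phagocytosis and efferocytosis (-0.21, 0.222) the bridging protein gene mfge8b fell (-1.91, SE 0.32). So did, among chemokine receptors and migration genes (0.12, 0.290), ccr6a (-1.77, SE 0.26) and cfl1l (-2.52, SE 0.37), and in the p53 list (-0.07, 0.391) btg2 (-1.93, SE 0.35). Of the chemokine receptor and migration genes past over all genes, 3 fell and 1 rose. The receptor tyrosine kinase gene tek rose (1.91, SE 0.34) among vascular and mural genes (-0.65, 0.881, camera pointing upward). The photoreceptor list had a median of 1.24 while camera pointed downward (0.352), and no member passed. The erythrocyte (-0.49, 0.881, camera pointing upward), lens (-0.98, 0.177) and pigment cell lists (0.07, 0.437) had no member past over all genes. Single omissions called 5 of these lists besides macrophage identity. They were the lysosome without unablated replicate 2, unablated replicate 3 or ablated replicate 2 (adjusted p = 0.0322, 0.0490 and 2.70e-06) and photoreceptors, downward and so against their median, without unablated or ablated replicate 2 (0.0107 and 0.00431). The others were antigen presentation without unablated or ablated replicate 1 (0.0476 and 0.0407), matrix and proteases without unablated replicate 3 (0.00979) and glycolysis without ablated replicate 3 (0.0212).

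**Figure D4:**
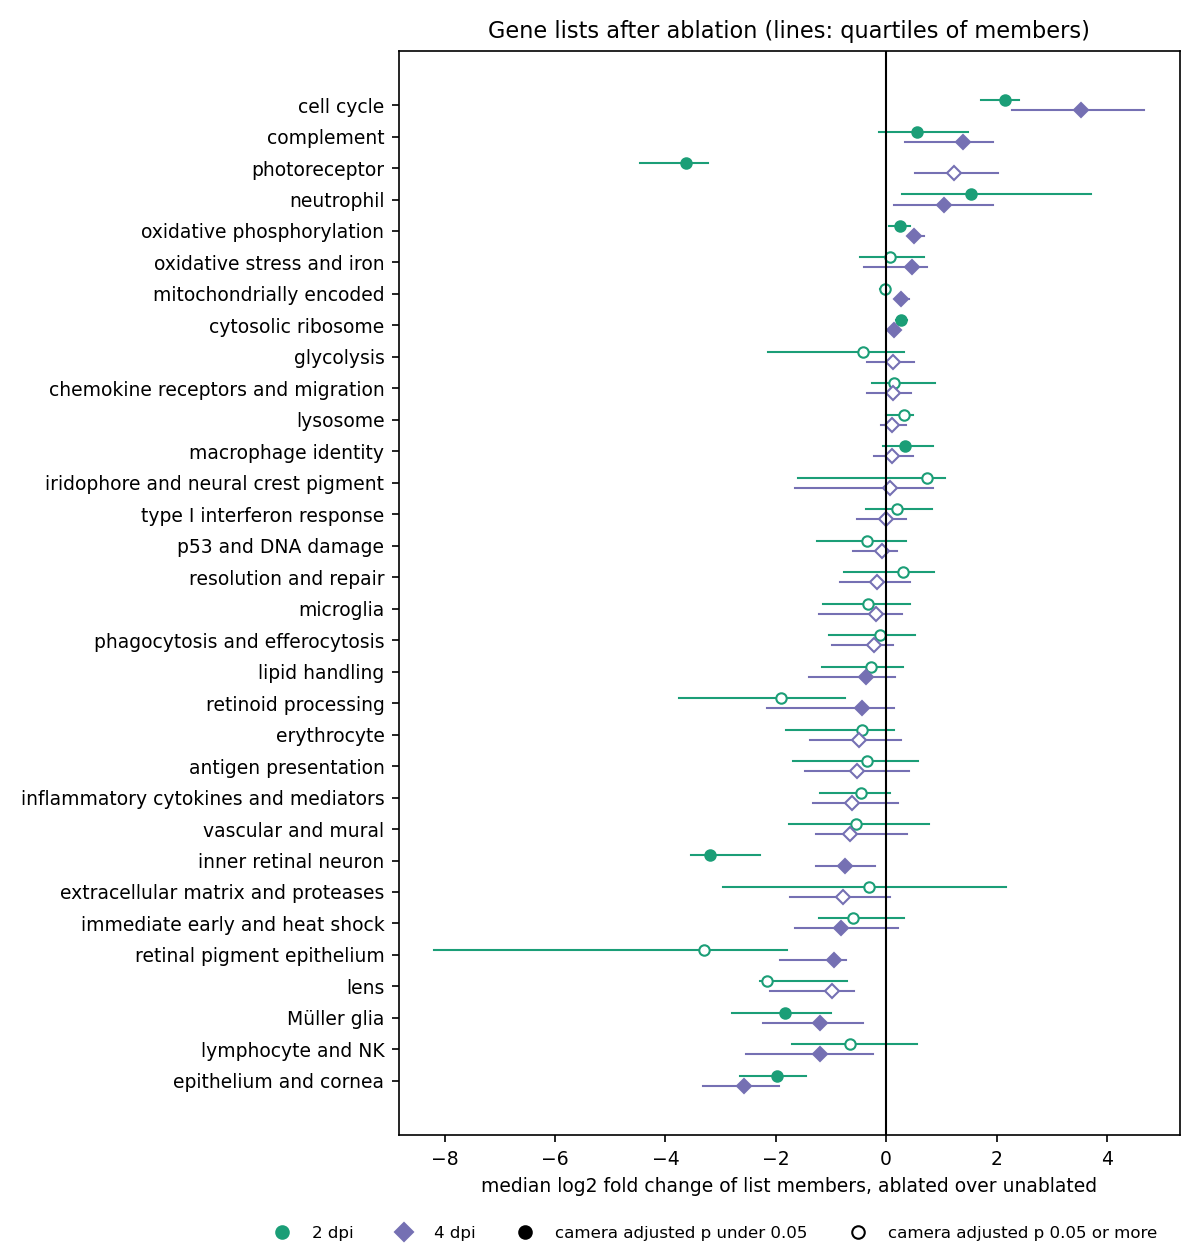
Median log2 fold change (ablated over unablated) of each of the 32 gene lists at 2 and at 4 dpi, with lines from the lower to the upper quartile of members and filled symbols for lists called by camera. The cell cycle list is highest at 4 dpi (3.53), and the epithelial list lies at -1.98 and -2.57.

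Whether the same genes responded at both times was examined over the 15262 genes tested at both. Of 297 genes that rose at 4 dpi, 289 (97.3%) were also higher at 2 dpi, and of 294 that fell, 289 (98.3%) were also lower, while 46.9% of all genes were higher at 2 dpi. The mean 2 dpi log2 fold change of the genes that rose lay 3.01 above that of the genes that fell. No other grouping of the 6 libraries at 2 dpi reached this (highest other 2.22). The two-sided exact permutation p was 0.1, the smallest that 20 labelings allow. These labelings exchange libraries across the title dates. Across genes, which are not independent replicates, the fold changes at both times correlated with Pearson's r = 0.51 and Spearman's rho = 0.58. With no call at 2 dpi, edgeR gave 0 genes called at both times. DESeq2 gave 468 higher and 130 lower at both, where independent lists would share 67.1 and 40.8. With limma voom they were 339 and 37, and on log2(TPM + 1) 388 and 7. The groups at the 2 times share no library.

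**Figure D5:**
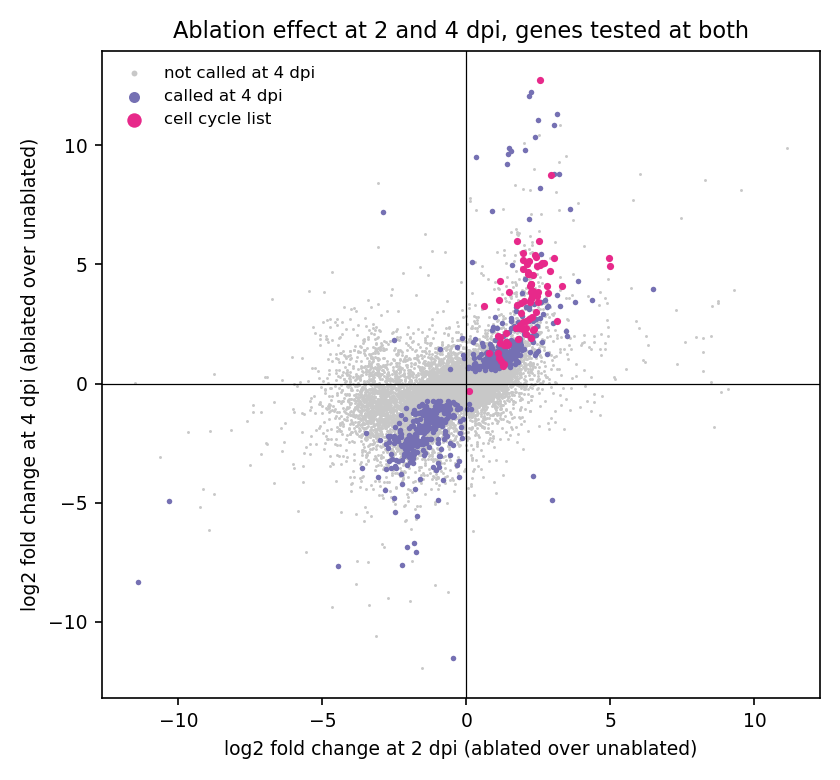
Log2 fold change (ablated over unablated) of each gene tested at both times, 2 dpi on the horizontal and 4 dpi on the vertical axis, with genes called at 4 dpi and cell cycle genes marked. Of 297 genes that rose at 4 dpi, 289 lie to the right of 0 at 2 dpi.

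No single gene's response was shown to differ between the times. The test of the difference, over all 12 libraries, called 0 of 18079 genes (edgeR, smallest adjusted p = 0.0577), with 1059 at an unadjusted p under 0.05, where 904 are due by chance. DESeq2 called 80 genes, limma voom 0 and limma on log2(TPM + 1) 0, and edgeR 3 with DESeq2's size factors, 5 with no filter and 3 with the strict filter. The test had little power: in a trial it recovered none of the genes planted at log2 1, 2 or 3. The smallest p belonged to kif23, kif14, haus4 (log2 difference 7.69, SE 1.04), ncaph and aspm, cell division genes at or near 0 counts in unablated libraries at 4 dpi. On the lower side stood the anthrax toxin receptor gene antxr2a (-2.42, SE 0.42), insig1 (-1.63, SE 0.32), dph5 (-1.42, SE 0.28), prps1a (-1.33, SE 0.26) and pa2g4b (-1.01, SE 0.21). The count was 19 without unablated replicate 2 at 4 dpi, and 3, 1 and 2 without unablated replicates 1, 2 and 3 at 2 dpi, and 3 without unablated replicate 3 at 4 dpi.

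In unablated eyes the named genes that fell most from 2 to 4 dpi, in the fit of all 12 libraries, were cell division genes. As a list cell cycle genes fell by camera, given below, but with an estimated correlation 0 of 32 lists were called (smallest adjusted p = 0.213). With only the 6 unablated libraries edgeR called 0 genes (smallest adjusted p = 0.320), with 1699 at an unadjusted p under 0.05 against 2756 in the fit of 12. Larval age and title date changed with time, so the 3 cannot be told apart. ncaph fell from 12.6 ± 10.6 to 0 CPM (at least 118-fold lower), kif23 from 12.3 ± 5.9 to 0 (at least 115-fold) and aspm from 11.9 ± 9.1 to 0 (at least 112-fold). ccnb1 (log2 fold change -8.14, SE 0.79, edgeR adjusted p = 0.00466) and hmmr (-3.88, SE 0.75) fell as well. The transporter gene slc43a3b (log2 fold change 3.59, SE 0.60), mtmr12 (2.60, SE 0.33), slc16a5a (2.42, SE 0.40), the lysyl oxidase gene loxl2b (2.33, SE 0.45) and pltp (2.22, SE 0.34) rose most. edgeR called 157 of 18079 genes, 47 higher and 110 lower at 4 dpi. With DESeq2's size factors 281 were called, 38 higher and 243 lower, and on log2(TPM + 1) 765, 536 higher and 229 lower. Without the libraries above 4% of photoreceptor counts 489 were called, 254 higher and 235 lower, so the balance of directions was not stable. The count was 24 and 493 without unablated replicates 2 and 3 at 2 dpi, and 14, 76 and 34 without unablated replicates 1, 2 and 3 at 4 dpi.

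In ablated eyes loxl2b (0.953 ± 0.273 to 29.9 ± 4.5 CPM, log2 fold change 4.96, SE 0.51, edgeR adjusted p = 0.0214) rose most between 2 and 4 dpi. Next came the ectonucleotidase gene entpd3 (3.44, SE 0.65), the phosphatidate phosphatase gene lpin1 (3.42, SE 0.65), the nuclear receptor gene nr1d4b (3.11, SE 0.48) and klf2a (3.08, SE 0.62). The tubulin genes tuba1b (-1.92, SE 0.31) and tuba8l (2100 ± 385 to 601 ± 175 CPM, -1.81, SE 0.31), ptrh2 (-1.80, SE 0.33), ube2s (-1.79, SE 0.33) and psmd10 (-1.79, SE 0.27) fell most. edgeR called 234 genes, 68 higher and 166 lower, against 186 with DESeq2's size factors (77 higher, 109 lower) and 448 on log2(TPM + 1) (181 higher, 267 lower). Without the libraries above 4% of photoreceptor counts it was 73, 44 higher and 29 lower. With only the 6 ablated libraries it was 6, all higher, and 1 of the 10 genes named here kept its call. It called 0 genes without ablated replicate 2 or 3 at 2 dpi, and 0 without ablated replicate 1, 2 or 3 at 4 dpi.

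As lists, cell cycle genes (median -2.58 in unablated and -1.48 in ablated eyes, camera adjusted p = 3.25e-33 and 4.43e-33) and oxidative phosphorylation (-0.76 and -0.46, 2.77e-37 and 1.17e-20) fell from 2 to 4 dpi in both conditions. With an estimated correlation the adjusted p = 0.214 in unablated and 0.458 in ablated eyes for both lists. Microglia genes rose in both (0.84 and 0.77, camera adjusted p = 1.81e-05 and 8.11e-07; adjusted p = 0.240 and 0.458 with an estimated correlation). So did those of the lysosome (0.47 and 0.27; 6.70e-07 and 5.26e-05; adjusted p = 0.360 and 0.618 with an estimated correlation) and macrophage identity (0.38 and 0.21; 5.71e-06 and 0.0272; adjusted p = 0.214 and 0.618 with an estimated correlation). The same held for resolution and repair (0.69 and 0.24; 4.00e-05 and 0.0271; adjusted p = 0.213 and 0.458 with an estimated correlation) and the cytosolic ribosome (0.39 and 0.18; 7.58e-19 and 5.23e-07; adjusted p = 0.240 and 0.627 with an estimated correlation). In unablated eyes, immediate early and heat shock genes (median 0.41, camera adjusted p = 0.000228), lipid handling (0.31, 0.00145), matrix and proteases (0.43, 0.00346) and the interferon response (0.42, 0.00825) rose and mitochondrially encoded genes fell (-0.32, 3.43e-06), each with adjusted p = 0.240 with an estimated correlation. There too chemokine receptors and migration genes (0.29, 0.00129; adjusted p = 0.360 with an estimated correlation) and the epithelial list (0.69, 0.00906; adjusted p = 0.595 with an estimated correlation) rose, and glycolysis (-0.52, 0.0302; adjusted p = 0.471 with an estimated correlation) and photoreceptors (-4.26, 0.0295; adjusted p = 0.833 with an estimated correlation) fell. In ablated eyes, the p53 list rose (0.23, 0.0243; adjusted p = 0.458 with an estimated correlation). These 10 lists were called in 1 condition and not in the other, which does not show a difference. Of the 10, the test of the difference called only mitochondrially encoded genes and photoreceptors (camera adjusted p = 0.000873 and 0.0370; adjusted p = 0.801 with an estimated correlation). In all, camera called 16 of 32 lists between the times in unablated eyes, 11 upward and 5 downward, and 8 in ablated eyes, 6 upward and 2 downward.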

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

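The explanations tested here, the photoreceptor covariate and the omission of libraries above 4% of photoreceptor counts were chosen after the results were seen; the regroupings of libraries and the list tests were fixed before.

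The rise of cell cycle genes in the sorts was weighed against 3 other sources. Dilution by RNA of the photoreceptor list gives a mean shift of 0.14 on the log2 scale at 2 dpi (other RNA is not counted in it), against a lower quartile of cell cycle genes of 1.72. A loss of other cells from the sorts that raised all macrophage genes alike would raise microglia genes too, whose upper quartile at 4 dpi was 0.29, against 2.27 for the lower quartile of cell cycle genes. Dividing retinal cells that keep Müller glia or inner neuron markers would bring these genes along, whose highest median was -0.75. This value cannot decide, because retinal RNA in the unablated sorts lowers these medians whether or not the ablated sorts held dividing retinal cells. At 2 dpi the inner neuron means were 1.52 to 5.06 log2(CPM + 1) in unablated and 0.639 to 2.87 in ablated libraries. Dividing retinal cells with these markers therefore stay open. The photoreceptor list, at 1.24 at 4 dpi, was not part of that test. Over both times no other labeling of the libraries reached the mean difference of 3.32 (highest other 2.73). The exact permutation p was 0.005, the smallest that 400 labelings allow. Within title dates the exact permutation p was 0.0125, the smallest that 160 allow. Its adjusted p over the 32 lists was 0.05, which did not pass. The source may be division in the sorted cells or entry of dividing cells, which these libraries do not separate. Dividing eye cells without the markers above, and a loss of non-dividing cells alone, were not tested.

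Photoreceptor RNA was unevenly spread over the sorts and could come from whole retinal cells, from free RNA or from outer segments taken up by phagocytes. Outer segments alone would bring no RNA of inner retinal neurons, yet across the 12 libraries the photoreceptor level rose with that of inner retinal neurons (r = 0.871, permutation p = 0.00036). It also rose with that of Müller glia (r = 0.884, permutation p = 0.00027) and the RPE (0.767, permutation p = 0.00074), and not with that of epithelium (-0.335, permutation p = 0.284) or macrophage identity (-0.504, permutation p = 0.0889). Without the farthest 2 libraries, unablated replicates 1 and 2 at 2 dpi, r was 0.813, 0.800, 0.736, -0.272 and 0.213 in that order. Outer segments alone are therefore unlikely to be the source, but outer segments beside other retinal RNA stay open. The photoreceptor share was 14%, 4.25%, 0.866% and 0.785% at similar inner neuron means of 3.35, 3.34, 3.44 and 3.22 log2(CPM + 1). These were unablated replicate 2 at 2 dpi, and ablated replicate 2 and unablated replicates 3 and 1 at 4 dpi. At 2 dpi the inner neuron and Müller glia means were lower in the ablated library of every title date, replicate 3 included (1.52 to 0.639 and 2.14 to 1.52 log2(CPM + 1)). The richest 2 unablated sorts are therefore not the only ones that differ.

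The ablation effect differed between the times for 7 lists by camera (median over members of the log2 difference in effect, 4 minus 2 dpi): cell cycle 1.16 (adjusted p = 2.05e-19), oxidative phosphorylation 0.20 (3.19e-05), mitochondrially encoded genes 0.23 (0.000873) and photoreceptors 4.78 (0.0370) upward, and the cytosolic ribosome -0.23 (9.70e-06), macrophage identity -0.31 (0.0278) and lymphocytes and NK cells -0.83 (0.0436) downward. With an estimated correlation none was called (adjusted p = 0.717 for lymphocytes and 0.801 for the others), and fry called none. For the cell cycle the larger difference went with a lower level in unablated eyes at 4 dpi, where the median fell by 2.58 since 2 dpi, against 1.48 in ablated eyes.

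Regroupings of the libraries gave few gene calls within a time or condition, but as many list calls. At 4 dpi the real grouping called 605 genes and the highest other 0, so 1 of 10 splits reached the real count, as in unablated eyes between the times (157 and 0, 1 of 10) and in ablated eyes (234 and 1, 1 of 10). At 2 dpi all called 0 (10 of 10). For lists the highest other split called 13 at 2 dpi and 15 at 4 dpi, against 10 and 15 (5 of 10 and 2 of 10 splits reached the real count). So few splits cannot give a share under 0.05. For the difference between the times the highest of 100 splits called 1103 genes and the next 413, against 0 (100 of 100 reached 0). The highest set unablated replicates 1 and 2 and ablated replicate 1 at 2 dpi, and ablated replicates 1 and 3 and unablated replicate 2 at 4 dpi, against the others. These were the libraries richest in photoreceptor RNA at 2 dpi and poorest at 4 dpi. Another 10 splits with the same side at 2 dpi called 0, and what made the difference was not tested.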

How the results depend on the processing

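The photoreceptor settings were chosen after the results were seen. At 2 dpi (0 genes) DESeq2 called 1486, voom 976, TPM 852 and all 12 libraries 1142; other settings and every omission 0. At 4 dpi (605) DESeq2 called 2317, voom 1553, TPM 1672, all 12 libraries 222, the covariate 1077, a block 0 (smallest adjusted p = 0.111), omissions 0 to 1420. Of the 80 named genes called, all kept their sign; 80 kept the call with DESeq2, 71 with voom, 20 with all 12 libraries and 0 with a block. The difference between the times (0): DESeq2 80, DESeq2's size factors 3, no filter 5, strict filter 3, photoreceptor-rich libraries out 53, omissions 0 to 19. Unablated eyes over time (157): 281 with DESeq2's size factors, 308 strict, 1408 DESeq2, 382 voom, 765 TPM, 11 block, 0 with 6 libraries, 489 without photoreceptor-rich ones (254 higher), omissions 14 to 493. Ablated eyes (234): 113 no filter, 393 strict, 1250 DESeq2, 2000 voom, 448 TPM, 135 block, 6 with 6 libraries, 73 without photoreceptor-rich ones (44 higher), omissions 0 to 185. Genes called at both times (0): 598, 376, 395 and 169 with DESeq2, voom, TPM and 12 libraries. Lists at 2 dpi (10): estimated correlation 0, fry 2, DESeq2's size factors 7, covariate 10 (8 shared), photoreceptor-rich out 5, omissions 6 to 14. Lists at 4 dpi (15): estimated correlation 0, fry 10, omissions 13 to 18. At 4 dpi the labels do not say whether replicate numbers pair libraries, and the r of same-number libraries (-0.17, -0.41 and -0.14) cannot settle it. A block by number there lost the inner neuron list (camera adjusted p = 0.0781) and added antigen presentation (0.0458) and inflammatory genes (0.0277). At 2 dpi the block by date changed no other call than those given. With photoreceptor-rich libraries out at 2 dpi, 1 unablated library stands against 3 and the spread is that of ablated ones alone, so little can be read from it; the ribosome and photoreceptor lists then changed direction (adjusted p = 0.843 and 0.293).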

Other observations

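The comparison of both times by a joint gene rule, the permutation of list means and the epithelial tests below were chosen after the results were seen.

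A joint rule asked for an unadjusted p under 0.01 and no overlap between conditions at each time. By it 348 genes were higher at both (47.2 due if the times were independent), 27 lower at both (7.02 due) and 0 opposite. The transglutaminase gene f13a1b, the coagulation factor XIII A chain found in macrophages, went from 141 ± 77 to 1244 ± 527 CPM at 2 dpi (log2 fold change 3.15, SE 0.60, edgeR adjusted p = 0.0896) and from 71.0 ± 32.2 to 934 ± 129 CPM at 4 dpi (3.72, SE 0.41, edgeR adjusted p = 0.0205), n = 3. scpp8 (6.49 and 3.96), the p38 kinase gene mapk12b (4.34 and 3.52), prr11 (3.78 and 3.43), the chemokine gene ccl39.5 (2.84 and 3.27) and cfbl (2.85 and 2.81) were higher at both. sat1a.1 (-2.69 and -3.25), the transcription factor gene znf703 (-2.44 and -3.53), pltp (-2.70 and -2.23) and btg2 (-2.32 and -1.93) were lower at both.

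List means over both times were compared by relabeling libraries within each time. Of 32 lists, 7 passed: complement (log2 difference 1.21), cell cycle (3.32), neutrophil (1.72) and oxidative stress and iron (0.32) higher and epithelium lower (-2.02), each at an exact permutation p = 0.005, the smallest that 400 labelings allow (adjusted p = 0.032), and the cytosolic ribosome higher (0.22) and phagocytosis lower (-0.39) at an exact permutation p = 0.01 (adjusted p = 0.0457). These labelings exchange libraries across the title dates at 2 dpi. With exchange only within dates none of the 32 lists passed: the smallest exact permutation p = 0.0125, the smallest that 160 labelings allow, had an adjusted p = 0.05, and it was reached by 6 of the 7 lists, all but the ribosome, and by the microglia and RPE lists.

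The lower epithelial genes at 4 dpi, among them epcam (1126 to 169 CPM), could come from fewer skin cells in the sorts, from fewer immune cells that carry epithelial genes, or from a change within cells. Carried-over keratinocytes would keep 13 keratins at a steady ratio to epcam. Among the 6 unablated libraries the ratio ranged 4.99-fold, between the bounds set of 3 and 10. It cannot decide, because krt8 and the krt18 genes made up much of the sum. In unablated replicates 1 to 3 the other 10, the skin keratins, gave 52.3, 106 and 480 of 602, 1822 and 3252 CPM at 2 dpi. At 4 dpi they gave 2079, 3315 and 314 of 4601, 5083 and 2280 CPM. A single population carrying epcam might account for the other genes, since 24 other epithelial genes followed epcam within groups at a median r = 0.645, above all 10000 random lists but short of the bound set of 0.7, while keratins followed it at 0.080. Of all genes that fell at 4 dpi, 190 of 306 followed epcam at r over 0.7, so genes of such a population may reach beyond the epithelial list. Skin keratins followed krt4 at r = 0.716, and their ratio to epcam ranged 31.0-fold, but these keratins were picked with the values in view, so neither value decides for or against skin cells.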
